A study of Mus musculus with 6 samples.

How the data were processed

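Total RNA from medullary thymic epithelial cells with high MHC class II (mTECs) of C57BL/6 mice was measured on Illumina bead arrays in a single colour (Cy3). Per the labels, RNA was isolated with a Qiagen RNeasy kit that included a DNase step on the column. There were 6 arrays, 3 from wild-type and 3 from Aire knockout mice. Any gate of the sort other than high MHC class II, and whether a sample is a single mouse or a pool, are not given in the sources used here, so each p-value describes the spread between these samples.

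The values analysed are a deposited table with 1 value per probe on each of the 6 arrays. The authors deposited them as normalized log2 values, and the submitters' processing notes name BeadStudio and lumi without versions. Which background correction, transform and normalization were used is not given in the sources used here. The 6 columns have nearly the same distribution (medians 6.55, maxima 14.43 to 14.46), so the arrays had been normalized to each other. Whether the scale is a plain log2 or the variance-stabilizing transform of lumi is not stated either, so a fold is 2 to the power of a difference of deposited values. A background level remains in the values, which compresses the folds of dim genes. The 24 value columns of the other deposited tables carry names that match no sample label. They were not used here, and the detection p-values among them were therefore not used as a filter.

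Background was estimated on each array from the values themselves, as the mode of all probes (6.21 to 6.22) and the spread below the mode (SD 0.194 to 0.195). The background bound was the mode plus 3 SD, which was 6.8 on every array. A probe was tested when it lay above this bound on at least 3 of the 6 arrays. This replaced a filter on detection p-values and a background correction with neqc that had been planned before the data were examined. Gene symbols came from the annotation of the array's probes, and probes with several symbols were treated as unnamed. Each gene was represented by its tested probe with the highest mean over the 6 arrays. No genome build is named for the arrays, so no coordinates are given. The order of genes along chromosomes was taken from the RefSeq annotation of the mouse assembly GRCm38.

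Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, genotype only, two-sided), with Benjamini-Hochberg adjustment over the 19547 tested probes and a threshold of 0.05. Gene lists were compared with all other tested named genes by limma's camera with a preset inter-gene correlation of 0.01, for lists with at least 5 tested members, adjusted over the lists. Camera was repeated with an estimated correlation, and fry was run in its place. Sex effects came from a limma model with genotype and sex, and the sex by genotype interaction from a model of the 4 cell means with 2 residual degrees of freedom. The version of statmod was 1.5.0. The precision is limited by the number of arrays.

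The comparisons, the 29 gene lists and the rule for naming genes were fixed before the data were examined. The rule names Aire, the 12 largest falls and the 12 largest rises among called genes whose groups did not overlap, up to 4 called members of each list with the largest changes, and the sex-linked genes. Clone names and similar symbols were left out of the largest changes. A few further genes are named where a count is small, and these were chosen after their values were seen. Where a gene lay above background on no array of a group, the fold is a lower bound. The bound sets the mean of the bright group against the mean, over the arrays of the dim group, of the higher of the gene's own value and the lowest signal above background.

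Alternatives planned before the data were examined were cyclic loess between arrays, no filter on dim probes, chip as a block, sex or date label as a covariate, chip and sex together, single chips, single sexes, the arrays with the later date label, the replicate number as a block, a trended and robust variance, array weights, probes averaged by gene, a log2 change of at least 1, and leaving out each array. With the date label as a covariate, the genotype change is that of the knockout arrays from wild-type replicate 3 alone. The arrays with the later date label give the same change, so these 2 alternatives are not independent. Scaling to 25 tested housekeeping genes, removal of the shift that normalization forces on unchanged probes, normexp on the antilog values (offset 16), other background bounds and counts of probes were chosen after seeing the data. Housekeeping scaling set the median level of these 25 genes equal on all arrays. It raised the median change of all tested probes from 0.10 to 0.28, although these genes had a median change of 0.021. It thus serves as a different offset and not as an anchor on unchanged genes. The forced shift was estimated by ranking the wild-type means, with the called falls set to their knockout means, back onto the wild-type distribution. The steps were tested on simulated data with the means and spreads of these arrays, 50 genes being changed at each size. A change of 0.5 log2 units was called for 26% of them, a change of 1 for 76% and changes of 2 and 3 for 100%, with 3 false calls among 15335 genes and unnamed probes. Only these genes were changed and the noise was independent between probes. In the data 9491 probes had an unadjusted limma p under 0.05, so the adjusted threshold was less strict there. These shares and the number of false calls therefore do not carry over to the real counts.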

Results

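The series profiled medullary thymic epithelial cells with high MHC class II (mTECs), the thymic stromal cells that display proteins of peripheral tissues to developing T cells. There were 3 wild-type arrays and 3 arrays from mice lacking Aire, a transcriptional regulator of these cells whose loss causes autoimmune disease. Of the 6 samples, 3 were female (wild-type replicates 1 and 3 and knockout replicate 2) and 3 male, so the sexes were not balanced between the genotypes. The main model held genotype only, with sex as an alternative. Each of the 2 beadchips held both genotypes. Wild-type replicates 1 and 2 carry an earlier date label than the other 4 arrays. Of the probes on the arrays, 19547 (41.9%) were tested, covering 11781 named genes and 3554 unnamed probes. Across the tested probes, arrays of the same genotype correlated with Pearson r between 0.984 and 0.994, and arrays of different genotypes between 0.909 and 0.935, where genes are not independent replicates. Between 18502 and 18647 probes per array stood above the background bound. The knockout mean was 52.7 probes higher (exact two-sided permutation p = 0.3, the smallest possible being 0.1), but the normalization fixes this count, so it carries no information on how many genes the cells expressed.

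The comparison of genotypes asks which transcripts of mTECs depend on Aire. Aire itself fell on both of its probes. The brighter probe (3520685) read 13.54, 13.66 and 13.40 log2 units on wild-type arrays 1 to 3, and 10.36, 10.30 and 10.01 on knockout arrays 1 to 3. The group values were 13.53 ± 0.13 (SD, n = 3) and 10.22 ± 0.19 (SD, n = 3), a log2 change of −3.31 (SE 0.12, adjusted p = 4.68e-08). The other probe (3830739) read 10.57 ± 0.43 and 8.25 ± 0.12, a change of −2.32 (SE 0.19, adjusted p = 1.06e-05). Both probes stayed above background on all 6 arrays.

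Among the 12 genes with the largest falls in the deposited values was Ppy, the pancreatic polypeptide hormone, which read 11.90 ± 0.16 (SD, n = 3) in wild type and was not above background on any knockout array. Ppy was at least 34.4-fold lower (adjusted p = 4.21e-09), where "at least" marks a fold measured against the lowest signal above background. Tff1, a trefoil peptide of stomach mucus, went from 12.64 ± 0.03 to 7.42 ± 0.20, which is 37.4-fold lower (log2 change −5.23, SE 0.12, adjusted p = 4.26e-09). Mpo, the peroxidase of neutrophil granules, was at least 30.4-fold lower, and Dcpp1, a salivary gland protein, at least 26.6-fold lower. The gut peptide Nts (neurotensin) was at least 23.4-fold lower and Defa20, a defensin of Paneth cells, at least 22.2-fold lower. Ctrb1, which encodes the pancreatic protease precursor chymotrypsinogen, changed by −4.87 (SE 0.20), and Pyy, the gut hormone peptide YY, by −4.85 (SE 0.14). Obp2a, an odorant-binding protein, was at least 22.9-fold lower, the serine protease Prss29 at least 20.7-fold, the beta-defensin Defb19 at least 18.4-fold and the trypsin gene Prss1 at least 18.1-fold. A second Prss1 probe lay above background on 1 knockout array.

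**Figure D1:**
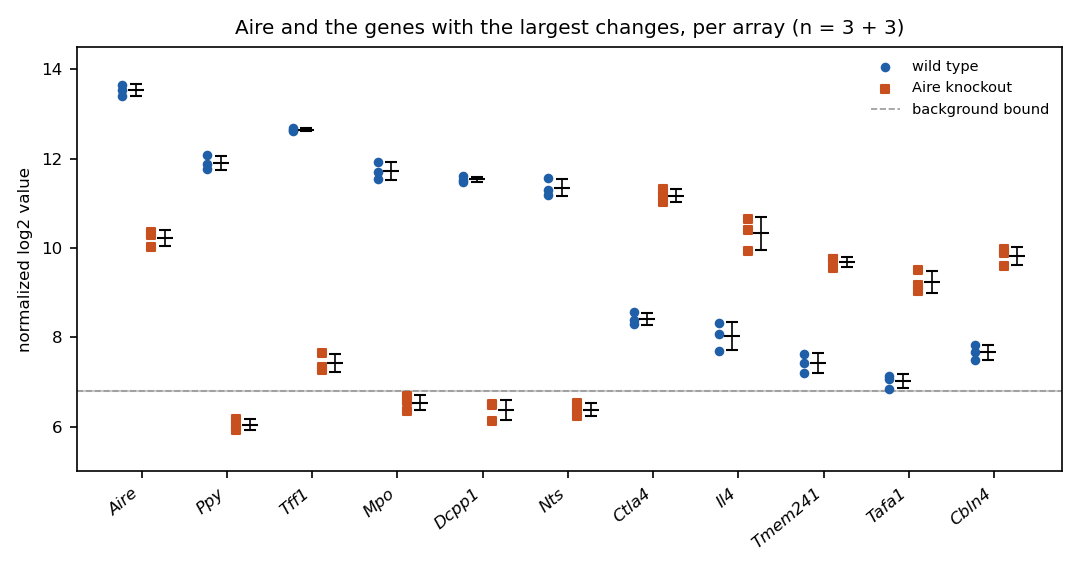
Normalized log2 values (vertical axis) of Aire and the genes with the 5 largest falls and 5 largest rises in these values, 1 point per array, with the mean and SD of the 3 wild-type and 3 knockout arrays beside the points. The dashed line is the background bound of 6.8. Ppy lies near 11.90 in wild type and below the bound in the knockout, while Ctla4 rises from 8.42 to 11.17.

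Genes known as Aire-dependent tissue antigens fell as a group. Of 21 tested members 18 fell and 1 rose, with the same counts adjusted over the list alone, and the median log2 change was −2.08 (camera adjusted p = 1.26e-12). With genes at their bound the median was −2.06. Besides Ppy and Dcpp1, Tff3, another trefoil peptide, was at least 14.1-fold lower, and Sst, the hormone somatostatin, at least 9.88-fold lower. The riser was Tgm3, a transglutaminase of keratinising cells (+0.73, SE 0.13, adjusted p = 0.00204). The median was −2.08 with chip as a block, −2.30 within chip 1 and −2.07 within chip 2. Of 16 antigens described as Aire-independent or tied to the transcription factor Fezf2, 6 fell and 3 rose, also when adjusted over the list alone (median −0.25, camera adjusted p = 0.188). This list did not pass, but all 6 fell by at least 1 log2 unit, as did only 958 of the 11781 tested named genes. The 6 antigens that fell included the apolipoprotein Apoc3 (−1.46, SE 0.23), the epidermal keratin Krt10 (−1.41, SE 0.17), transthyretin (Ttr, −1.41, SE 0.12) and the cartilage collagen Col2a1 (−1.28, SE 0.13). Those that rose were Mbp, a myelin protein (+0.62, with 2 other probes at −0.21 and +0.06 that did not pass), Pld1 (+0.47) and Csmd1 (+0.33).

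Genes of the pancreas and endocrine organs showed the lowest list median. Of 26 tested, 24 fell and none rose, with the same counts adjusted over the list alone (median −2.42, and −2.08 with genes at their bound; camera adjusted p = 1.21e-18). In the liver list 16 of 20 fell and 2 rose, the same adjusted over the list alone (median −1.995, −1.757 with bounds, adjusted p = 2.85e-09). Apoa1, the main protein of high-density lipoprotein, changed by −3.53 (SE 0.14). Itih4 was at least 9.54-fold lower, Itih3 at least 6.75-fold and the drug-metabolising enzyme Cyp1a2 at least 6.29-fold, whereas prothrombin (F2, +0.64) and Itih1 (+0.52) rose. All 15 tested salivary and lacrimal gland genes fell, also when adjusted over the list alone (median −1.57, −1.30 with bounds, adjusted p = 2.85e-09). They included Lcn3, a lipocalin (at least 8.63-fold lower), Bpifa2 (at least 3.10-fold) and Bpifa1 (−2.10, SE 0.14), secreted proteins of saliva and airways.

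In the intestine and stomach list 22 of 26 genes fell and none rose, also adjusted over the list alone (median −1.45 with or without bounds, adjusted p = 6.86e-13). Pgc, the precursor of a gastric protease, changed by −4.27 (SE 0.09), and Gkn1, a gastric mucosal protein, was at least 10.5-fold lower. In the testis, seminal vesicle and prostate list 16 of 21 fell and 3 rose (16 and 4 adjusted over the list alone; median −1.24, −0.96 with bounds, adjusted p = 1.14e-06). Sbp was at least 15.2-fold lower, the seminal vesicle protein Svs4 at least 8.38-fold and the epididymal lipocalin Lcn8 at least 8.73-fold, and Spink1, a trypsin inhibitor, changed by −2.41 (SE 0.15). The 3 that rose were the sperm genes Zpbp (+0.44) and Tnp2 (+0.42) and the tubulin Tuba3a (+0.39). In the eye, brain and nerve list 17 of 23 fell and 4 rose (18 and 4 adjusted over the list alone; median −0.88, −0.69 with bounds, adjusted p = 8.62e-07). Calb2, a neuronal calcium-binding protein, was at least 14.49-fold lower, the lens crystallin Crygs at least 4.30-fold, and Npy, neuropeptide Y, changed by −3.72 (SE 0.11). The synaptic genes Snap25 (+0.85) and Syt1 (+0.47), Tph1 (+0.66) and Mbp rose. With no filter on dim probes the medians of the liver, testis and nerve lists were −0.77, −0.24 and −0.56, with their calls kept. The call of the nerve list ended when only genes above background on all 6 arrays were tested (median −0.25, adjusted p = 0.27, in a range of 2.38e-11 to 0.27 over all alternatives).

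Genes of the skin and of keratinising epithelium fell in 24 of 32 cases and rose in 3 (24 and 4 adjusted over the list alone; median −0.94, −0.93 with bounds, adjusted p = 2.04e-07, but adjusted p = 0.0837 with an estimated correlation). Lce3c, a cornified envelope protein, was at least 10.6-fold lower, the kallikrein protease Klk5 at least 8.96-fold, Krt13, a keratin of stratified mucosa, at least 5.84-fold and the cornification caspase Casp14 at least 3.35-fold. Il1rn, the antagonist of the interleukin-1 receptor, rose by 1.53 (SE 0.24), as did Tgm3 and the desmoglein Dsg1a (+0.42). Microfold and goblet-secretory genes fell in 11 of 21 cases and rose in none (11 and 1 adjusted over the list alone; median −0.69, −0.52 with bounds, adjusted p = 3.44e-05). Lactotransferrin (Ltf) changed by −3.89 (SE 0.29), the mucin Muc5ac was at least 8.26-fold lower and Tff2 changed by −2.62 (SE 0.11). With an estimated correlation, 8 lists kept their call, all of them lower: Aire-dependent antigens, pancreas, liver and intestine (each adjusted p = 0.0172), eye, brain and nerve (0.0257), and salivary gland, testis and microfold genes (each 0.0305). The lists share genes, so they are not independent results. Of the 21 tested Aire-dependent antigens 15 are also in another list. So are 9 of 16 Aire-independent antigens, 9 of 21 microfold genes, 8 of 30 chemokines, 6 of 26 pancreas genes and 6 of 20 liver genes. With fry in place of camera, all 14 lists passed. Its directional test, used here, asks whether a list's genes changed in a shared direction and not whether they changed more than other genes. With fry 6 more lists passed, all with the direction down: Aire-independent antigens and Aire partners (each adjusted p = 0.00351), epithelial identity (0.0108), neuroendocrine (0.0106), dendritic cell and macrophage (4.94e-04) and erythroid genes (0.00207). Of these 6, the medians of the epithelial, neuroendocrine and Aire-partner lists turn positive with housekeeping scaling, and that of the erythroid list is positive in the main values.

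Epithelial and thymic epithelial identity genes fell in 6 of 17 cases and rose in 2, also when adjusted over the list alone (median −0.10, +0.08 with housekeeping scaling, camera adjusted p = 0.455). Those that fell included the keratins Krt19 (−1.95, SE 0.19), Krt5 (−1.83, SE 0.28) and Krt14 (−0.70, SE 0.13) and the surface protein Ly6d (−1.10, SE 0.14), and those that rose were Itga6 (+0.48) and Pax9 (+0.43). Tuft cell genes, of a chemosensory cell type, fell in 6 of 14 cases, also adjusted over the list alone, among them Lrmp (−0.87, SE 0.23), Avil (−0.80, SE 0.17), the ion channel Trpm5 (−0.77, SE 0.18, a second probe at −0.23 not passing) and the kinase Dclk1 (−0.66, SE 0.16). The call of Lrmp ended without knockout replicate 1 (adjusted p = 0.0611) and without knockout replicate 2 (0.0607). In males only the changes were smaller, at −0.295 for Lrmp, −0.484 for Avil, −0.406 for Trpm5 and −0.379 for Dclk1. The tuft list did not pass (median −0.37, camera adjusted p = 0.091), but did with chip as a block (adjusted p = 0.0268), without knockout replicate 3 (0.0146) and without wild-type replicate 2 (0.014), in a range of 0.00389 to 0.856 over all alternatives. Of 14 neuroendocrine genes 4 fell and 4 rose (5 and 4 adjusted over the list alone; median −0.14, +0.04 with housekeeping scaling, adjusted p = 0.455). The transcription factor Neurog3 was at least 2.74-fold lower and the granin Scg2 at least 2.84-fold and Chgb, another granin, at least 1.93-fold, while the synaptic proteins Snap25 and Syp (+0.79) rose.

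**Figure D2:**
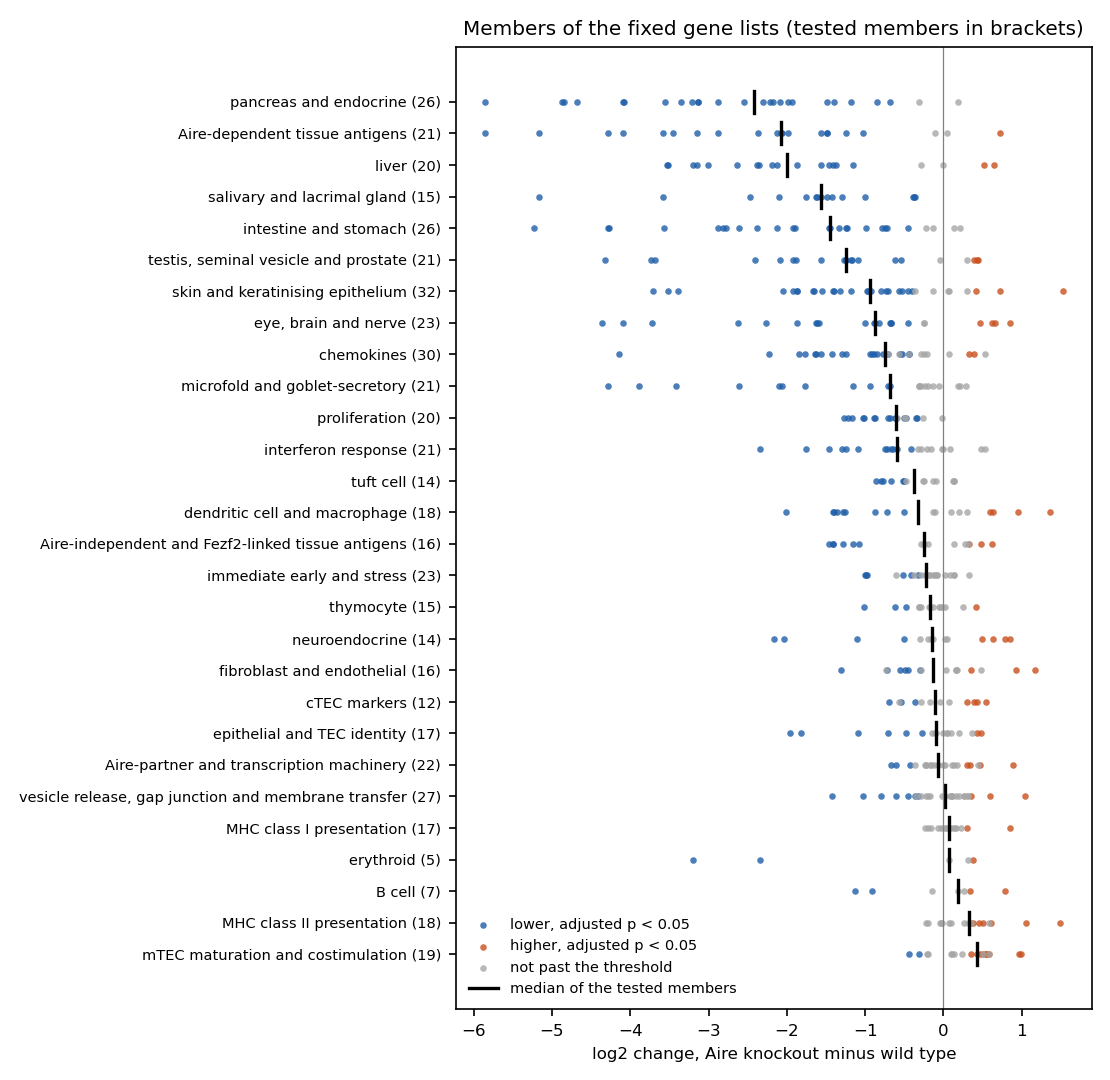
Log2 change, knockout minus wild type (horizontal axis), of every tested member of the 28 lists with a list test, coloured by call, with the median of each list as a black bar and the number of tested members in brackets. Pancreas and endocrine genes (median −2.42) and Aire-dependent antigens (−2.08) lie lowest, and mTEC maturation genes (+0.43) lie highest. Medians near 0 change sign with the scaling for the lists of MHC class I, epithelial identity, cTEC, vesicle release, neuroendocrine, Aire-partner, thymocyte, fibroblast and erythroid genes.

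Chemokine genes fell in 20 of 30 cases and rose in 2 (22 and 2 adjusted over the list alone; median −0.74, camera adjusted p = 1.72e-06, but adjusted p = 0.0837 with an estimated correlation). Xcl1, a chemokine that attracts dendritic cells carrying the receptor XCR1, went from 11.25 ± 0.09 to 7.10 ± 0.07 (SD, n = 3 each), a change of −4.14 (SE 0.10, adjusted p = 4.31e-09). Ccl8 changed by −2.22 (SE 0.20), the B cell attractant Cxcl13 by −1.84 (SE 0.14) and Ccl9 by −1.76 (SE 0.13), whereas Ccl25 (+0.39) and Cxcl16 (+0.33) rose. Interferon response genes fell in 12 of 21 cases and rose in none (13 and 0 adjusted over the list alone; median −0.59, −0.46 with bounds, adjusted p = 4.08e-04, but adjusted p = 0.163 with an estimated correlation). The antiviral genes Rsad2 (−2.34, SE 0.21), Isg15 (−1.75, SE 0.10) and Ifit2 (−1.46, SE 0.11) fell, as did the interferon gene Ifnb1 (−1.29, SE 0.17). Beside these, Cd14 of the dendritic cell and macrophage list (−2.01, SE 0.12) fell.

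Proliferation genes fell in 15 of 20 cases and rose in none (18 and 0 adjusted over the list alone; median −0.61, adjusted p = 3.46e-05, but adjusted p = 0.442 with an estimated correlation). With housekeeping scaling 9 fell, and within chip 1 and chip 2 7 and 3. The replication factor Mcm5 changed by −1.27 (SE 0.19) and the mitotic genes Cenpa by −1.21 (SE 0.19), Cdc20 by −1.17 (SE 0.14) and Plk1 by −1.03 (SE 0.16). Another Cenpa probe (−0.22) and 2 other Cdc20 probes (−0.39 and −0.49) did not pass. Of 23 immediate early and stress genes 6 fell and none rose (5 and 0 adjusted over the list alone). They included Hmox1, heme oxygenase (−1.01, SE 0.15), Ier3 (−0.99, SE 0.10) and the transcription factor Atf3 (−0.97, SE 0.21), and the heat shock protein gene Hsph1 (−0.51, SE 0.12), whose call ended with housekeeping scaling. This list did not pass (median −0.22, adjusted p = 0.0764), but did without wild-type replicate 1 (adjusted p = 0.0148) and without knockout replicate 1 (0.032), and had an adjusted p of 0.05 with chip as a block, in a range of 3.73e-04 to 0.636 over all alternatives.

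Fewer genes rose by much. Ctla4, an inhibitory receptor known from T cells, rose most among named genes, from 8.42 ± 0.14 to 11.17 ± 0.15 (SD, n = 3 each), which is 6.75-fold higher (adjusted p = 1.15e-07). The cytokine gene Il4 was 4.92-fold higher (SE 0.20 on the log2 scale), and Ly9, a receptor of lymphocytes, 3.68-fold higher (SE 0.16). The median of the thymocyte list was −0.17, and the T cell receptor component Cd3g changed by −1.01 (SE 0.19). Tmem241 rose by 2.26 (SE 0.13), the secreted protein genes Tafa1 by 2.22 (SE 0.14) and Cbln4 by 2.16 (SE 0.13), and Rgr, an opsin, by 2.03 (SE 0.13). Stac (+1.95), the sialidase Neu2 (+1.93), the nicotinic receptor subunit Chrnb2 (+1.92), the phosphatase Dusp15 (+1.85) and the growth factor Fgf10 (+1.84) completed the 12 largest rises. A probe with no gene symbol (106020017), singled out after its value was seen, rose from 6.37 ± 0.08 to 11.23 ± 0.18, at least 21.6-fold.

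MHC class II presentation genes rose in 7 of 18 cases and fell in none (10 and 0 adjusted over the list alone; median +0.33, camera adjusted p = 0.0123, but adjusted p = 0.186 with an estimated correlation). H2-Eb2 rose by 1.49 (SE 0.21) and H2-Ob, which modulates peptide loading, by 1.06 (SE 0.10). Rfx5, a transcription factor of MHC class II genes, rose by 0.61 (SE 0.11) and H2-DMb1 by 0.50 (SE 0.09). The chains H2-Ab1 (+0.10) and H2-Eb1 (+0.08) and the invariant chain Cd74 (−0.03, a second probe at +0.17), named after their values were seen, did not pass. Among mTEC maturation and costimulation genes 9 of 19 rose and 2 fell (10 and 2 adjusted over the list alone; median +0.43, adjusted p = 0.0344, but adjusted p = 0.442 with an estimated correlation). Cd52 rose by 0.99 (SE 0.22) and Icosl, a costimulatory ligand, by 0.96 (SE 0.18), the signalling adaptor Traf6 by 0.58 (SE 0.19) and Cd83 by 0.55 (SE 0.15), whereas the chemokine Ccl22 (−0.44) and the receptor Ltbr (−0.31) fell. The call of this list ended without wild-type replicate 1 (adjusted p = 0.0502) and without knockout replicate 2 (0.0562), in a range of 0.00299 to 0.442 over all alternatives. In males only the list's median was +0.18 and its call ended (0.182). With the forced shift taken out 4 genes rose and 2 fell, and with housekeeping scaling 11 and 0. With the date label as a covariate the change of Cd52 was 0.50 and its call ended (0.168). The call of Traf6 ended without wild-type replicate 1 (0.0952) or 3 (0.102) and without knockout replicate 1 (0.109) or 2 (0.135), and that of Cd83 without knockout replicate 2 (0.0831). Both also ended with the forced shift taken out. Beside these lists, genes of the dendritic cell and macrophage list moved both ways, with Batf3 (+1.35, SE 0.14), Fcer1g (+0.95), Ccr7 (+0.63) and Zbtb46 (+0.59) higher. Of 17 MHC class I genes 2 rose and none fell (1 and 0 adjusted over the list alone; median +0.07, −0.01 with the forced shift taken out, adjusted p = 0.455). They were the peptide-loading factor Tapbp (+0.85, SE 0.20) and the chaperone Canx (+0.30, SE 0.09). With the date label as a covariate the change of Tapbp was 0.48 and its call ended. The arrays with the later label only give the same change, since both fits set the knockout arrays against wild-type replicate 3 alone. The call of Canx ended with chip as a block (adjusted p = 0.0557), with the forced shift taken out (0.482), without knockout replicate 1 (0.0599), 2 (0.0857) or 3 (0.082) and without wild-type replicate 3 (0.0708).

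The series title names transfer of antigen from mTECs to dendritic cells. Of 27 genes for vesicle release, gap junctions and membrane transfer 7 fell and 3 rose, also when adjusted over the list alone (camera adjusted p = 0.84). The balance turned with the scaling, with 3 lower and 5 higher under housekeeping scaling (median +0.20) and 11 and 2 with the forced shift taken out (median −0.09). The median was +0.02, and −0.07 and −0.05 within chips 1 and 2, while the mean was −0.09 and the test direction down. The lipoprotein receptor Scarb1 (−1.42, SE 0.14), the vesicle protein Mfge8 (−1.02, SE 0.13) and Rab27a, a regulator of vesicle release (−0.80, SE 0.14), fell. The gap junction gene Gjb2 (+1.04, SE 0.25), Pdcd6ip (+0.60) and Lamp1 (+0.35) rose. With the date label as a covariate the changes of Gjb2 and Rab27a were 0.65 and −0.52 and their calls ended (adjusted p = 0.202 and 0.0566), and that of Gjb2 also with chip and sex in the model (0.0938). Of 22 Aire partners and transcription factors 3 fell and 4 rose, also adjusted over the list alone (median −0.07, +0.11 with housekeeping scaling, adjusted p = 0.941). Hexim1, an inhibitor of transcription elongation, changed by −0.66 (SE 0.09) and the chromatin remodeller Chd4 by −0.60 (SE 0.13), although 2 other Chd4 probes (−0.06 and −0.14) did not pass and the call ended with housekeeping scaling. The coactivator Crebbp rose by 0.89 (SE 0.13) and the deacetylase Sirt1 by 0.46 (SE 0.12). With the date label as a covariate the changes of Chd4 and Sirt1 were −0.515 and 0.395 and their calls ended. That of Sirt1 also ended with chip and sex in the model (adjusted p = 0.0552).

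Markers of other cells gave no list past the threshold of camera. Thymocyte genes fell in 3 of 15 cases and rose in 1, also adjusted over the list alone (median −0.17, +0.01 with housekeeping scaling, camera adjusted p = 0.455), with Satb1 the riser (+0.42), a call that ended with the forced shift taken out. Besides Cd3g, the fallers were Cd3d (−0.61, SE 0.17) and the kinase Zap70 (−0.48, SE 0.14), and both calls ended with housekeeping scaling. They also ended without knockout replicate 1 (adjusted p = 0.0641 and 0.102) and 2 (0.0651 and 0.0889), and that of Zap70 without wild-type replicate 1 (0.0636) or 3 (0.0591). Dendritic cell and macrophage genes fell in 9 of 18 cases and rose in 4 (9 and 5 adjusted over the list alone; median −0.32, −0.21 with bounds, adjusted p = 0.207), the complement genes C1qb (−1.41, SE 0.10) and C1qc (−1.40, SE 0.13) and the lysozyme Lyz1 (−1.36, SE 0.18) among the fallers. Of 7 B cell genes 2 fell and 2 rose, also adjusted over the list alone (median +0.19, mean −0.09, test direction up, adjusted p = 0.941), Fcmr changing by −1.13 (SE 0.09), Cd79a being at least 1.27-fold lower, and Blk changing by +0.79 (SE 0.09) and Cd79b by +0.34 (SE 0.09). The call of Cd79b ended without knockout replicate 1 (0.0612) or 2 (0.0603) and with the forced shift taken out. Fibroblast and endothelial genes fell in 6 of 16 cases and rose in 3 (6 and 4 adjusted over the list alone). Their median was −0.13, +0.05 with housekeeping scaling, their mean −0.09 and their test direction up (adjusted p = 0.941), with the collagen Col1a1 at −1.31 (SE 0.32) decorin (Dcn) at +1.17 (SE 0.12), the angiopoietin receptor Tek at +0.93 (SE 0.10) and Egfl7 at −0.72 (SE 0.17, a second probe at −0.01). With the date label as a covariate the calls of Col1a1 (−0.89, adjusted p = 0.181) and Egfl7 (−0.59, 0.121) ended, as they did on chip 2 alone (0.392 and 0.28). Of 5 erythroid genes 2 fell and 1 rose, also adjusted over the list alone (mean −0.95, test direction down, adjusted p = 0.445). Their median was +0.08, −0.07 with cyclic loess and −0.08 with the forced shift taken out. The embryonic globin Hbb-bh1 was at least 7.195-fold lower and Slc4a1, the anion exchanger of red cells, at least 4.53-fold, while Alas2 rose (+0.38, SE 0.09), a call that ended with the forced shift taken out, and with housekeeping scaling this list passed (adjusted p = 0.0165, in a range of 0.00207 to 0.58 over all alternatives). Of 12 cortical thymic epithelial (cTEC) markers 3 fell and 4 rose, also adjusted over the list alone (median −0.11, +0.07 with housekeeping scaling, test direction up, adjusted p = 0.975). Pdpn (−0.70, SE 0.21) and the Notch ligand Dll4 (−0.55, SE 0.11) fell, and Cd83 and the endocytic receptor Ly75 (+0.43, SE 0.11) rose. The call of Dll4 ended with housekeeping scaling, that of Ly75 without knockout replicate 2 (0.0594) and with cyclic loess or the forced shift taken out. That of Pdpn ended with chip as a block (0.0545), without wild-type replicate 1 (0.059) or 2 (0.0706) and without knockout replicate 1 (0.0769) or 2 (0.0855).

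Over all tests, 3168 of 15335 genes and unnamed probes were lower and 2980 higher in the knockout. Among the 11781 named genes, 2726 (23.1%) were lower, by a median of −0.76, and 2153 (18.3%) higher, by a median of +0.50. By at least 1 log2 unit 958 were lower and 193 higher, and by at least 2 units 278 and 7. Of the 958, 435 (45.4%) were above background on no knockout array. Of the 193, 5 were above background on no wild-type array, namely Acot12, Cnr2, Olfr1140, 1700003P14Rik and 2810404M03Rik. In 6400 named genes (54.3%) the groups did not overlap, where chance gives 10%. For 15 genes, probes were called in opposite directions.

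**Figure D3:**
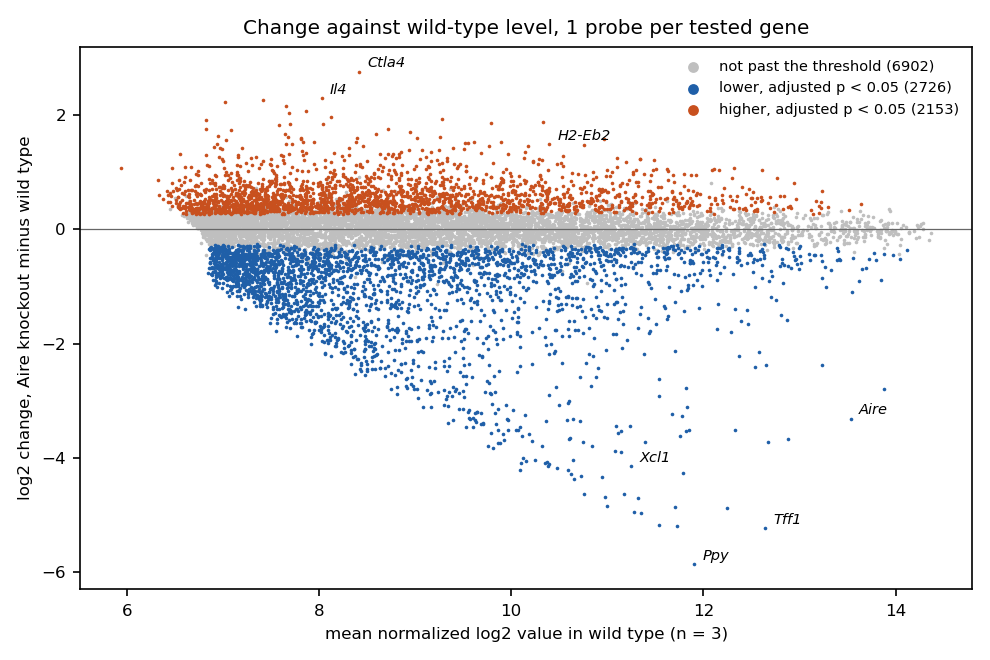
Log2 change, knockout minus wild type (vertical axis), against the mean log2 value in wild type (horizontal axis), 1 probe for each of the 11781 tested named genes, coloured by call. Among the 2726 lower genes Tff1, above background in both groups, lies at −5.23 and Ppy, not above background in the knockout, is at least 34.4-fold lower, while the highest of the 2153 higher genes is Ctla4 at +2.75. The slanted lower edge of the cloud is where knockout values reach background.

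With chip as a block 2905 genes and unnamed probes were lower and 2569 higher. Within chip 1 (2 wild-type, 1 knockout) the counts were 1373 and 400, and within chip 2 (1 and 2) 1563 and 726. Chip and sex together in the model ended 11 of 123 calls of named probes. They were Traf6, Cd83, Tapbp, Canx, Ly75, Gjb2, Lrmp, Sirt1, Hsph1, Zap70 and Cd79b. With the date label as a covariate 21 of 123 calls of named probes ended. Besides those of Cd52, Tapbp, Gjb2, Rab27a, Col1a1 and Egfl7 these were Traf6, Cd83, Canx, Pdpn, Dll4, Ly75, Lrmp, Trpm5, Dclk1, Chd4, Sirt1, Cd3d, Zap70, Cd79b and Alas2. The changes of Traf6, Canx, Ly75, Lrmp, Trpm5 and Zap70 were no smaller with this covariate than in the main fit, and those of the rest were smaller. In the fits within a chip the lone array of a genotype is assumed to vary like the pair of the other, so their counts carry less weight. The fit with the date label as a covariate likewise rests on wild-type replicate 3 as its only wild-type reference for the genotype change. All 12 lower lists and both higher lists kept the sign of their medians with chip as a block and within each chip. The lower lists ranged from −2.40 to −0.54, from −2.35 to −0.46 and from −2.45 to −0.57 in these fits, and the higher lists had medians of 0.24 to 0.39. The number of higher genes was 1947 without knockout replicate 1 and 1889 without knockout replicate 2. The split of calls moved with the scaling, and also with other settings given further below. Main values had a median change of +0.10 over all tested probes and 51.5% of the calls among genes and unnamed probes lower. That share was 67.3% with cyclic loess (median 0.000 over all probes, 1811 higher), 75.6% with the forced shift taken out (−0.06, 1421 higher) and 33.5% with housekeeping scaling (+0.28, 1954 lower). Housekeeping scaling raised every change by the same amount, although the housekeeping genes' own median change was 0.021 in the main values. Its share shows only how far such an offset moves the calls. Among genes and unnamed probes changed by at least 1 log2 unit the share lower was 81.1%, and 86.7%, 89.7% and 65.8% under these scalings. The 14 called lists kept the sign of their medians under all 3, but the split of calls moved in several lists. With housekeeping scaling and with the forced shift taken out, the lower and higher counts were 6 and 5, and 9 and 2, for Aire-independent antigens, 0 and 10, and 2 and 5, for MHC class II genes, and 0 and 2, and 2 and 1, for MHC class I genes. They were 4 and 3, and 6 and 1, for epithelial identity, 1 and 4, and 4 and 0, for cTEC markers, 3 and 4, and 6 and 2, for neuroendocrine genes, and 1 and 5, and 7 and 2, for Aire partners. They were 3 and 1, and 10 and 0, for immediate early genes, 1 and 1, and 4 and 0, for thymocyte markers, 2 and 2, and 2 and 1, for B cell markers, 3 and 4, and 6 and 2, for fibroblast and endothelial markers, and 2 and 2, and 2 and 0, for erythroid genes. Interferon genes went to 10 and 2 with housekeeping scaling, and no testis gene was higher with cyclic loess or with the forced shift taken out.

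The labels give the sex of each sample, and the expression of sex-linked genes was compared with it. Xist, the RNA that silences an X chromosome, read 9.21 to 9.58 in the 3 female samples and 6.33 to 6.54 in the 3 male samples, a log2 change, male minus female, of −3.07 (SE 0.11, limma with genotype, adjusted p = 1.27e-04). Eif2s3y, a gene of the Y chromosome, read 6.07 to 6.39 in females and 7.34 to 7.72 in males (+1.22, SE 0.14), which did not pass (adjusted p = 0.259). Kdm5d was not above background on any array, and the tested Uty probe read 7.18 ± 0.19 (SD, n = 3) in females and 7.23 ± 0.23 in males. Of 3 tested sex-linked probes, only that annotated to Uty was called higher in the knockout (+0.33, SE 0.10, adjusted p = 0.0255), also when adjusted over the list alone. That probe was above background in all 3 females and the other 2 Uty probes were at background, so it does not report the Y-linked gene. Xist (−0.84) and Eif2s3y (+0.49) did not pass between genotypes. Their directions are those that the unequal sexes of the groups would give. Xist was the only probe past the threshold between the sexes, and 679 had an unadjusted p under 0.05. For the interaction of sex and genotype, limma called 0 of 19547 probes, with 426 at an unadjusted p under 0.05. With 2 residual degrees of freedom this test can miss differences of moderate size, and with housekeeping scaling it called 2 probes.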

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

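Housekeeping scaling, removal of the forced shift, normexp on the antilog values, the filters on other background bounds and the count of probes were chosen after seeing the data, and all other alternatives before. The fall of Aire kept its sign and its call under every alternative run (−3.48 to −2.82, largest adjusted p = 8.06e-04), and so did that of the Aire-dependent antigens (medians −2.39 to −1.49, largest adjusted p = 0.0172). No called list or called named gene reversed its direction, but among all called genes 2 went from higher to lower with probes averaged by gene. The balance of the counts did turn. Counted by probe, 3463 were lower and 4045 higher. The share of calls lower was 51.5% in the main values. It was 48.3% with array weights, 47.9% with probes averaged by gene and 49.7% without wild-type replicate 1. For genes above background on all arrays it was 41.9%, and with housekeeping scaling 33.5%. For the gene lists, 749 values kept their side of the threshold, 10 lost and 24 gained a call, and of the named gene probes 2957 kept their side and 199 lost a call.

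The main counts of genes and unnamed probes were 3168 lower and 2980 higher. A log2 change of at least 1 left 1115 and 260. Fits on fewer arrays, which have fewer residual degrees of freedom and in which a lone array is assumed to vary like the others, gave 1373 and 400 on chip 1, 1563 and 726 on chip 2, 1606 and 557 in females, 1541 higher in males and 1796 higher on the arrays with the later date label. The date label as a covariate gave 2054 and 1320 and ended 21 of 123 calls of named probes, although the changes of Traf6, Canx, Ly75, Lrmp, Trpm5 and Zap70 did not shrink. Other scalings gave 1811 higher with cyclic loess, 1421 higher with the forced shift taken out and 1954 lower with housekeeping scaling, which also called 2 probes for the interaction of sex and genotype. Testing only genes above background on all arrays gave 1747 lower, since genes that fell to background were no longer tested. Of 14 lists past the threshold, 8 remained with an estimated correlation, and why the other 6 did not was not tested. With fry in place of camera, which tests each list without reference to other genes, 20 lists passed (18 lower, 2 higher).

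Leaving out 1 array gave 2548 to 3168 lower and 1889 to 3087 higher, an Aire change of −3.38 to −3.21, 13 to 15 lists, and medians of −2.179 to −2.002 for the Aire-dependent antigens. The lowest higher counts came without knockout replicate 2 (1889) and 1 (1947), and the cause was not tested. With the replicate block, 3158 were lower and 2882 higher. Replicates with the same number did not pair, since their residuals correlated at 0.203, −0.06 and −0.016.

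The quantile normalization without background correction, the authors' full normalized matrix and the filters on detection p-values were not run, since the columns they need match no sample label. The value table planned as an alternative became the main one. Signal over background limits the folds: 435 of the 958 genes lower by at least 1 log2 unit were above background on no knockout array, so their falls are lower bounds.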

Other observations

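The tests of gene families, of neighbouring genes' stems by first letters, of dendritic cell and B cell markers, of the date label across chips, and of the rises of at least 1 log2 unit against normalization were chosen only after the results were seen. Gene families were formed by symbol stem, and 179 with at least 8 tested members were compared with all other genes (Fisher's exact test, one-sided, 358 tests). Of these, 13 held more fallen genes than the test expects by chance. The test counts members as independent, although near-identical copies can share probes and many members lie side by side. Its p-values may therefore be too small. All 20 tested kallikrein genes (Klk), proteases of skin and of glands, fell, with a median of −1.62 and of −1.54 with genes at their bound (adjusted p = 3.28e-11). All 10 late cornified envelope genes (Lce, median −1.91, −1.63 with bounds) and all 10 small proline-rich genes (Sprr, −1.76 with or without bounds), families that build the outer skin, fell too (adjusted p = 2.59e-05 each). Of 41 keratin genes 34 fell (Krt, −1.13, −0.96 with bounds, adjusted p = 2.88e-13), among them Krt13 (at least 5.84-fold lower). Of 39 cytochrome P450 genes 28 fell and 3 rose (Cyp, −0.78, −0.53 with bounds, adjusted p = 1.82e-08), the risers being Cyp26a1, Cyp27a1 and Cyp4f16. Beta-defensins fell in 14 of 18 cases and rose in 3 (Defb, −0.88, −0.52 with bounds, adjusted p = 7.32e-05), with Defb33 at +1.49 and Defb42 at +1.23. Chemokine genes of the Ccl type (16 of 21), Spink inhibitors (8 of 8), carbonic anhydrases (Car, 10 of 12), collagens (Col, 15 of 25) and aquaporins (Aqp, 7 of 9) fell as well. These 11 families stayed past the threshold with cyclic loess, with housekeeping scaling, with the forced shift taken out and without each array, and their medians kept their sign. The Prss and Slc families were past it in the main test but not in all of these.

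Higher families were Snx (12 of 24, median 0.33, adjusted p = 0.0133), Lrrc (11 of 24, 0.0453) and Zfp (46 of 167, 0.0467). None passed with cyclic loess, with the forced shift taken out or without knockout replicate 3 (0.344, 0.0556 and 0.48). Snx also did not pass without wild-type replicate 2 (0.679) or knockout replicate 1 (0.121), Lrrc without wild-type replicate 1 (0.139), and Zfp without any 1 array (0.426 to 1). With housekeeping scaling only Snx passed.

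Against the 3168 genes and unnamed probes lower and 2980 higher, the highest count of any other split of the 6 arrays was 1 probe, in the split of females from males. In each direction 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. Every other split mixed wild-type and knockout arrays on each side, so differences between the genotypes added to the spread within the sides. Low counts in those splits were therefore largely fixed in advance and do not show how many calls chance would give.

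Among rises, 193 named genes rose by at least 1 log2 unit and 1960 by less. When many genes fall, ranking arrays onto 1 distribution lifts the others, by an estimated 0.172 log2 units in the median for unchanged tested probes. With that shift taken out all 193 larger rises were still called higher, with a median of 1.06 in place of 1.22 (quartiles 0.93 to 1.24 in place of 1.09 to 1.42). The largest estimated lift was 0.232, so a rise of at least 1 could hardly lose its call. The count of 193 was thus largely fixed in advance, and shows only that this estimated lift is smaller than these rises. Of the 193, 113 still reached 1, and counting those still called, in place of those still reaching 1, was decided after both were seen. Of the smaller rises a share of 0.452 was still called, their median going from 0.48 (quartiles 0.38 to 0.63) to 0.31 (0.20 to 0.46). These calls ended because the correction lowers the change itself, so normalization may account for many of those calls. The 25 housekeeping genes do not settle the offset. Their median change was only 0.021, yet scaling to their median level raised the median change of all tested probes from 0.10 to 0.28. How many smaller rises are real therefore stays open.

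Other cells in the sort were weighed for the larger rises, since Ctla4, Il4 and Ly9 are known from lymphocytes and the labels name no gate other than high MHC class II, which dendritic cells and B cells would pass. Against a median rise of 1.22, thymocyte markers had a median of −0.17 (SD 0.34, 1 of 15 higher; Thy1 11.83 to 11.54, Cd8b1 10.58 to 10.27), so more thymocytes are an unlikely source. Fibroblast and endothelial markers together had a median of −0.128 (SD 0.65, 3 of 16 higher; Dcn 11.19 to 12.36, Col6a1 10.53 to 9.80). This argues against both cell types rising together but not against 1 of them alone, since members ran from −1.312 to 1.166. Whether falls of markers within mTECs hid added cells in any of these lists was not tested. Dendritic cell and macrophage markers together had a median of −0.319 (SD 0.96, 4 of 18 higher; Laptm5 13.61 to 13.48, Lyz2 12.49 to 12.69), which argues against both cell types rising together. The list cannot decide on dendritic cells alone. Its members moved both ways, with Batf3, Fcer1g, Ccr7 and Zbtb46 higher and 9 lower, among them Cd14, C1qb, C1qc and Lyz1. Which of them mark dendritic cells alone was not set beforehand. B cell markers had a median of 0.191 (SD 0.70, 2 of 7 higher; Blnk 12.61 to 12.80, Cd72 11.30 to 11.15), too few and too mixed to decide. Every tested marker of these 4 lists was above background on all wild-type arrays, and only Thy1 is in more than 1 list. Dendritic cells, B cells, fibroblasts or endothelial cells alone, and a change within mTECs lacking Aire or in the share of their subsets stay open.

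Fallen genes lay next to each other more often than in random orders. Of neighbouring pairs among 11773 placed genes 908 had both members lower, against a mean of 629 in 10000 permutations (one-sided permutation p = 1e-04, the smallest they can give). Near-identical copies that share probes could add pairs, but without pairs of the same symbol stem 651 remained against 591 (permutation p = 8e-04), and 635 against 591 when the first letters were compared (permutation p = 0.01). Higher genes lay together as well (541 against 369 without such pairs, permutation p = 1e-04). The longest run of genes lower by at least 1 log2 unit held 12 genes of the Lor and Sprr region on chromosome 3 (median −1.76 with or without bounds). Copies with like symbols are thus excluded only as the whole cause, related genes with unlike symbols remain in the counts, and no biological explanation was tested.

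The earlier date label is on 2 of the 3 wild-type arrays and on no knockout array. On chip 1 the label goes with the genotype, while on chip 2, which shares no array with chip 1, every array carries the later label. The 1773 genes and unnamed probes called on chip 1 changed on chip 2 by 0.937 times as much in the median (quartiles 0.798 to 1.05, where a date effect alone would give 0), and 1764 of them (99.5%) had the same sign. The date is thus an unlikely source of most of these changes, although chip 2 holds 1 wild-type array and smaller changes, not called on chip 1, were not covered. With the date label as a covariate Cd52 (0.99 to 0.50), Tapbp (0.85 to 0.48), Gjb2 (1.04 to 0.65), Rab27a (−0.80 to −0.52) and Col1a1 (−1.31 to −0.89) were among the 21 of 123 called named probes that lost their call. The changes of Traf6 (0.72), Lrmp (−0.989), Trpm5 (−0.886), Canx (0.334), Ly75 (0.459) and Zap70 (−0.484) were no smaller than in the main fit. Those of the rest of the 21 were smaller. With this covariate the change is that of the knockout arrays from wild-type replicate 3 alone. Neither a lost call nor a smaller change therefore points to the date by itself. The role of the date was not settled for any of the 21.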
